A study of Folsomia candida with 12 samples.

How the data were processed

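Total RNA was measured from pools of about 30 animals of the springtail Folsomia candida, each pool taken from 1 jar with 30 g of soil. Springtails are small wingless soil arthropods that are widely used in soil toxicity tests. The animals' age is given as 23 days for all samples, per the labels, and they had spent 1, 2 or 7 days in soil spiked with pentachlorophenol (PCP), a chlorinated phenol once used as a pesticide and wood preservative, or in untreated soil. The 12 samples were 3 PCP jars for each exposure time and 3 jars of untreated soil, 1 for each time. The series' design text speaks of 3 replicates per time point, and 1 control array per time was analysed here. The 3 control arrays were therefore treated as 1 control group that spans the 3 times. Each sample is a separate jar, so the spread between arrays of a PCP group holds differences between jars. At PCP day 2 and day 7 it also holds differences between slides, since these groups were divided over slides. The spread of the control group also holds differences between days. The soil concentration of PCP was not given in the sources used here.

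Per the labels' protocols, 875 ng of total RNA per sample was amplified and labelled with Cy3, and each sample was hybridised alone to an Agilent array. The deposited scanner files hold spot intensity values from Agilent Feature Extraction. The submitters' processing notes name version 9.1, while the file headers give protocol modules of version 10.7.1.1. Per the file headers, the processed intensity of a spot is its brightness after background subtraction and detrending within the array, with no scaling between arrays, and spots not distinguishable from background carry a small positive surrogate value. The mean spot intensity and the local background intensity, deposited in the same files, were used for an alternative background correction. The authors' deposited series table holds log2 values for the same arrays. Its columns had equal medians and sorted values that differed by at most 0.005, so the arrays had been brought to a common distribution, and its values correlated with log2 processed intensity at 0.996 to 0.999 per array. No fold change direction or centring per probe is stated for that table, and it was used as an alternative.

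Each array held 42916 spots, of which 41499 were not control spots. These spots made up 5925 probes, 5917 with 7 spots each and 8 with 10 spots each. The files do not pair the probes with genes, and 0 of the probe names matched the 27231 genes of the reference gene table for this species, so probes are given by their identifiers. For the same reason the 28 gene lists fixed before the data were examined, covering detoxification, stress response, energy metabolism, moulting and other processes, had no members on the array that could be recognised, and no set test was run. Control spots and spots marked as outliers by Feature Extraction, 1.33% to 2.52% of the spots per array, were left out. The number of saturated non-control spots was 0.

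A probe was called detected on an array when at least 50% of its kept spots there were well above background. Because under 25% of probes were detected on any array, each array's log2 processed intensity was scaled to the 75th percentile over the 989 probes detected on all 12 arrays. Spots of a probe were averaged on the log2 scale, and no pseudocount was added. The 1364 probes detected on at least 3 of the 12 arrays, 23% of all probes, were tested. For arrays, their number limits the precision, and signal over background limits what can be measured.

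Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over the 1364 probes and a threshold of 0.05. All 12 arrays in 4 groups entered 1 fit with 8 residual degrees of freedom. The comparisons were PCP at day 1, 2 and 7 against control, the 3 differences between PCP days, and, in a second fit with day as a covariate, all 9 PCP arrays against the 3 control arrays. A group on which a probe was not well above background on any array has only a bound. The fold is then given as at least the ratio of the brighter group's mean to the dim group's mean, where each dim value was replaced by the lowest signal among detected probes of its array if that was higher. These choices, the alternatives and the rule for named probes were fixed before the data were examined. With no gene names, the rule names at most 2 probes with the highest and 2 with the lowest log2 fold change among those past the threshold in a comparison, and where none passes, up to 2 in each direction of smallest p. Against control at day 1, 2 and 7, the rule also requires that the PCP arrays do not overlap the control arrays. For probes named by it there, such separation is therefore no added support. Where a comparison had 5 or fewer calls, the remaining one is named as well, and its choice after its values were seen is stated. Intervals given are 95% confidence intervals of the fit.

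The procedure was tested on simulated arrays with the real probe means and independent noise, in which 200 of the 1364 probes were changed. The noise used each probe's SD as estimated by eBayes, and there were no slide or day differences. For PCP day 1 versus control the procedure recovered 58.2% of the 2-fold, 92.5% of the 4-fold and 100.0% of the 8-fold changes, with 6.18% of calls false. For PCP versus control adjusted for day, the shares were 77.6%, 97.0% and 100.0%, with 1.61% of calls false. At most 18 probes were called in a real comparison, and the adjusted threshold is stricter where fewer probes change. The share of real changes that is found may therefore be lower than in the simulation.

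The files place the 12 arrays on 3 slides of 4 arrays. Slide 1 held the 3 PCP day 1 arrays and PCP day 2 replicate 1, slide 2 held PCP day 2 replicates 2 and 3 and PCP day 7 replicates 1 and 2, and slide 3 held the 3 control arrays and PCP day 7 replicate 3. Every slide was scanned once and all on 1 date, so scan date could not be fitted as a separate block. Alternatives fixed before the data were examined covered background correction (normexp with an offset of 50), quantile normalization, the filter on dim probes, outlier spots kept in, the authors' table, slide as a block, the replicate number as a block, array weights, the same-day control alone, only the arrays compared, a fit without trend, a further limit of 2-fold, no day term, and leaving out each array. The 75th percentile over all probes, slide as a random block and fits within single slides were added after seeing the data. Plots were drawn with matplotlib.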

Results

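Expression was measured on 12 one-colour arrays, 3 each for animals kept 1, 2 or 7 days in PCP-spiked soil and 3 for animals kept in untreated soil. Between 18.9% and 24.5% of the 5925 probes were detected per array, with 1331 ± 103 probes in the control group, 1180 ± 36 at PCP day 1, 1140 ± 38.4 at day 2 and 1314 ± 21.9 at day 7 (mean ± SD, n = 3 each). The median local background lay between 19 and 25 intensity units on every array. The 75th percentile of the log2 signal of probes detected on all arrays ranged from 9.33 to 11.03 before scaling, and it was highest on the control array of day 1. The root mean square SD of the tested probes was 0.62 log2 units between the control arrays, against 0.40, 0.50 and 0.42 between the PCP arrays of day 1, 2 and 7.

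The first 2 principal components held 33.9% and 25.9% of the variance. PCP day 2 replicate 1, the only day 2 array on slide 1, correlated at 0.984, 0.986 and 0.978 with the PCP day 1 arrays of that slide across the 1364 tested probes, which are not independent replicates. Its correlation with PCP day 7 replicate 2, on slide 2, was 0.985, and with the other day 2 arrays 0.963 and 0.980. Arrays of different groups on the same slide correlated at 0.980 on average over 10 pairs, and arrays of the same group on different slides at 0.978 over 4 pairs. For 9 of the 12 arrays the best correlated array was of the same slide. For 7 it was of the same group, and each of these was also of the same slide. The control array of day 7 correlated with the control array of day 1 at 0.952 and with PCP day 1 replicate 3 at 0.986.

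**Figure D1:**
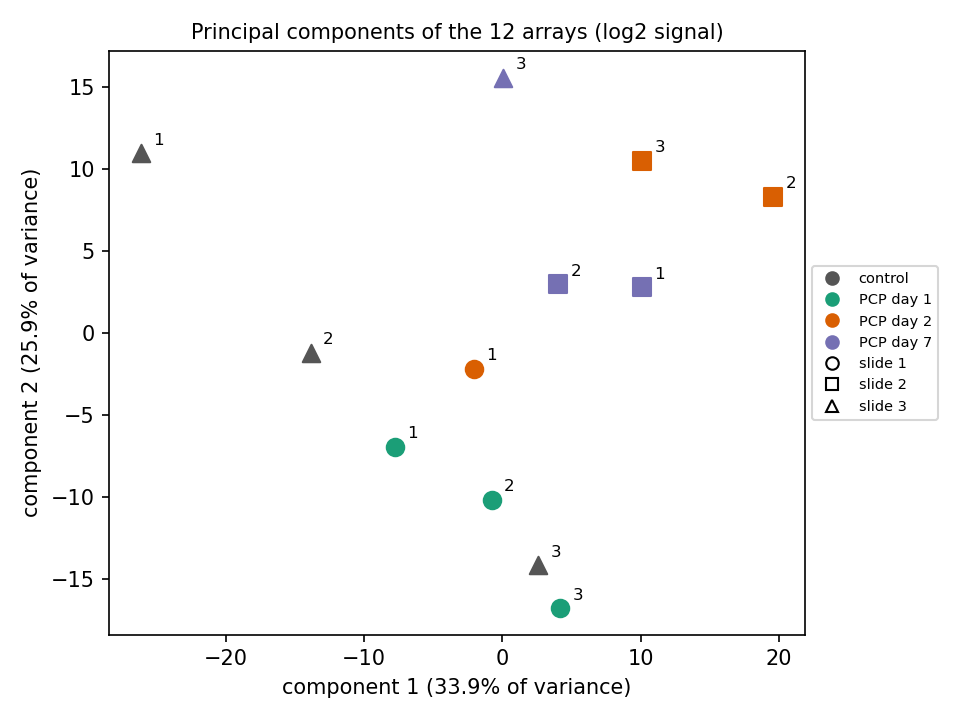
Principal components of the 12 arrays, from scaled log2 signals of the tested probes, with component 1 (33.9% of the variance) against component 2 (25.9%). Colours are groups, symbols are slides and numbers are replicates. The control arrays spread from -26.13 to 2.61 on component 1, and PCP day 2 replicate 1 lies at -2.04 on component 1 and -2.16 on component 2.

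Which transcripts differed after 1 day in PCP soil was asked with the PCP day 1 and control arrays. Probe F_candida_1627 rose from 6.87 ± 0.32 to 9.48 ± 0.18 log2 units (SD, n = 3 each), a 6.12-fold increase with a log2 fold change of 2.61 (SE 0.42, adjusted p = 0.0281). Probe F_candida_513 rose from 9.23 ± 0.23 to 10.64 ± 0.38, which is 2.64-fold (log2 fold change 1.40, SE 0.22, adjusted p = 0.0281). F_candida_92, named after its values were seen, rose from 5.87 ± 0.11 to 7.11 ± 0.12 (log2 fold change 1.24, SE 0.20, adjusted p = 0.0281). All 3 PCP day 1 arrays lay above all 3 control arrays for these probes, which the naming rule required of F_candida_1627 and F_candida_513. At day 2 and day 7, F_candida_1627 averaged 7.08 ± 0.48 and 6.61 ± 0.98, and its difference from control was 0.22 (interval -0.70 to 1.13) and -0.26 (interval -1.17 to 0.65). Of 1364 tested probes, 3 were higher and 0 lower past the threshold, and 220 (16.1%) had an unadjusted p under 0.05. The groups did not overlap for 266 probes (19.5%), where chance gives 10%. No slide held both groups, so a fit with slide as a block linked them only through PCP day 2 and day 7 arrays. There 0 probes passed, and the log2 fold changes of F_candida_1627, F_candida_513 and F_candida_92 were 0.41 (SE 0.68), 0.95 (SE 0.55) and 0.40 (SE 0.39). These wider SEs leave open how much of each change is a slide difference. F_candida_92 lost its call in 13 of 22 alternatives (adjusted p 5.5e-05 to 1.00), among them quantile normalization (log2 fold change 0.99, adjusted p = 0.0986), the authors' values (0.98, adjusted p = 0.111) and normexp (0.55, adjusted p = 1.00). With the percentile taken over all probes, the log2 fold changes of F_candida_1627 and F_candida_513 were 2.25 and 1.04 (adjusted p = 0.105 and 0.256). Without the day 1 control, the adjusted p of F_candida_1627 and F_candida_92 was 0.0506. The count was 0 without any 1 of the 3 day 1 arrays, 1 (lower) without the day 2 control and 187 (128 higher, 59 lower) without the day 7 control.

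After 2 days, F_candida_1565 was the 1 probe past the threshold against control. Its signal rose from 2.99 ± 0.36 to 7.45 ± 0.86 log2 units (SD, n = 3 each), a 22.1-fold increase (log2 fold change 4.46, SE 0.53, adjusted p = 0.00518), and all 3 day 2 arrays lay above all 3 control arrays. At PCP day 1 the same probe averaged 2.99 ± 0.70, was detected on 2 of 3 arrays and differed from control by 0.00 (interval -1.17 to 1.17). F_candida_1565 was detected on all 3 control arrays, at 3.20, 2.58 and 3.19 for day 1, 2 and 7. In total 301 probes (22.1%) had an unadjusted p under 0.05, 243 of them higher and 58 lower (91 higher and 209 lower with the percentile taken over all probes), and 240 (17.6%) did not overlap between groups. No slide held both groups, so with slide as a block they were linked through the PCP day 7 arrays. In that fit 2 probes passed, both lower, and the log2 fold change of F_candida_1565 was 5.15 (SE 0.99, adjusted p = 0.102). It was 1.69 (adjusted p = 0.529) under normexp, 1.58 (adjusted p = 0.0706) under normexp with quantile normalization and 4.88 (adjusted p = 0.0641) against the day 2 control alone, and adjusted p lay between 6.0e-07 and 0.529 over 21 alternatives. The count was 219 (184 higher, 35 lower) without the day 7 control and 38 (35 higher, 3 lower) without PCP day 2 replicate 1, and under quantile normalization it was 21 (17 higher, 4 lower).

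After 7 days the 1 probe past the threshold was again F_candida_1565, at 6.65 ± 0.88 log2 units against 2.99 ± 0.36 in control (SD, n = 3 each). This is 12.6-fold higher (log2 fold change 3.66, SE 0.53, adjusted p = 0.0338), with all 3 day 7 arrays above all 3 control arrays. On slide 3, which held the 3 control arrays and PCP day 7 replicate 3, the difference within the slide was 3.88 (adjusted p = 0.423 in a fit of that slide alone, where 0 probes passed). Over all probes, 212 (15.5%) had an unadjusted p under 0.05 and 256 (18.8%) did not overlap between groups. The day 7 fold change of F_candida_1565 had adjusted p between 3.3e-05 and 1.00 over the 22 alternatives, was 1.15 (adjusted p = 1.00) under normexp, 3.76 (adjusted p = 0.126) without the day 1 control, 3.45 (0.134) without the day 2 control, 3.29 (0.0751) without PCP day 7 replicate 1 and 3.55 (0.0856) without replicate 3. The count was 0 in those fits except 1 without the day 2 control, 13 (all higher) without the day 7 control, 2 (both lower) with slide as a block, and 11 (1 higher, 10 lower) with the percentile taken over all probes.

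**Figure D2:**
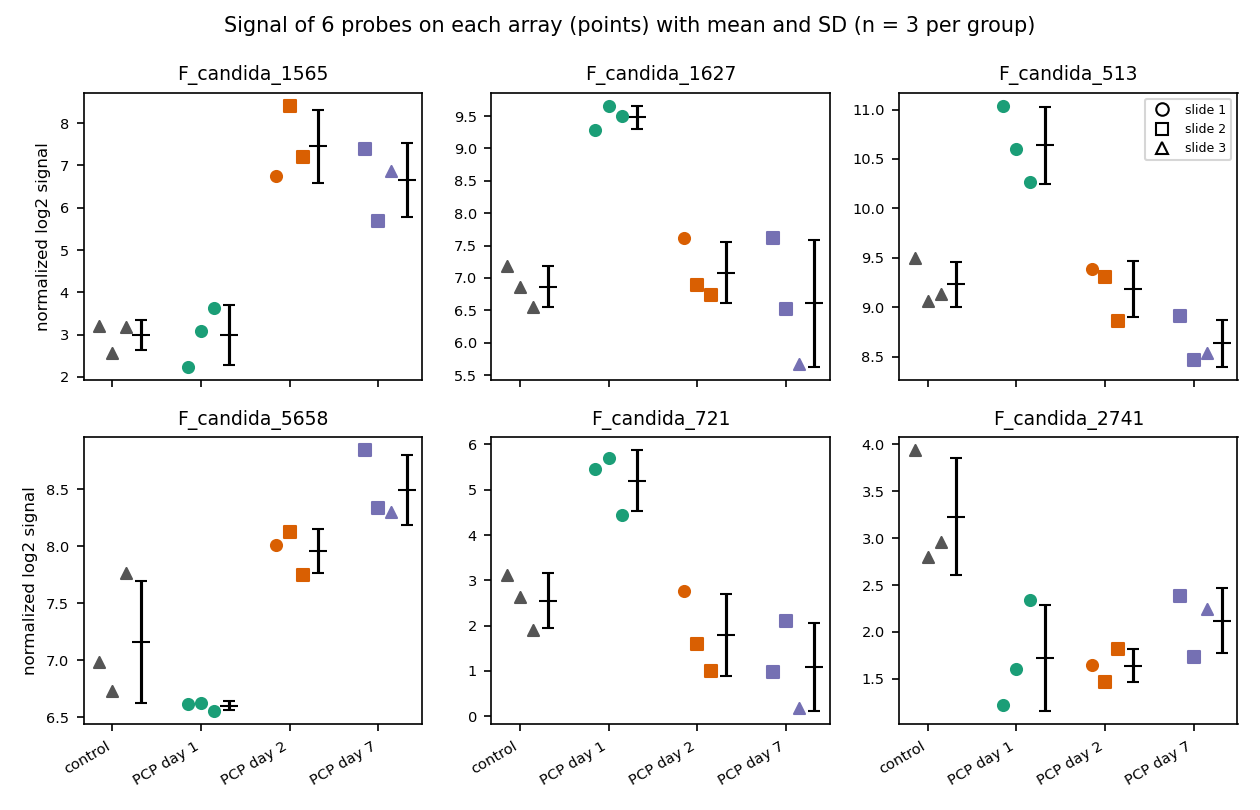
Scaled log2 signal of 6 probes on each of the 12 arrays (points, with the symbol giving the slide) and the mean and SD of each group (dash and bar, n = 3). F_candida_1565 averages 2.99 in control and at PCP day 1 against 7.45 at day 2 and 6.65 at day 7, while F_candida_1627 averages 9.48 at day 1 and at most 7.08 in the other groups. F_candida_721 and F_candida_2741 were not well above background on any array of some PCP groups.

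Fold changes against the shared control arrays correlated across probes at 0.55 for day 1 and 2, 0.43 for day 1 and 7, and 0.88 for day 2 and 7. Unchanged groups simulated against the same number of shared controls gave 0.67, 0.67 and 0.66. The covariance exceeded the simulated one by 0.07 and 0.21 for day 1 and 2 and for day 2 and 7, and lay 0.00 from it for day 1 and 7. The 3 controls are too few to be split into parts of 2 or more arrays, so part of any excess may come from them. The simulation held no slide differences, while day 2 and day 7 have 2 arrays each on slide 2 and all controls lie on slide 3, so an excess can also hold a difference between slides. Day 2 and day 7 shared 1 called probe, F_candida_1565, and both lists use the same control arrays. Unchanged groups simulated with shared controls and no slide differences shared 0 calls in 100 draws, an outcome close to fixed beforehand because unchanged probes rarely pass. Independent lists would share 7.3e-04. Neither value allows for the effects and the shared arrays together.

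Whether PCP and control differed on average over the 3 times was asked with all 9 PCP arrays against the 3 controls, adjusted for day. The fit assumes 1 effect for all days, so it does not test whether the effects were alike. Effects that differ by day add to its spread, as for F_candida_1565 (log2 fold change 2.71, adjusted p = 0.0903 in limma). In limma, 0 of 1364 probes passed, the smallest adjusted p was 0.0592, and 278 probes (20.4%) had an unadjusted p under 0.05, 238 higher and 40 lower. This balance depended on the scaling, with 163 higher and 57 lower under quantile normalization and 69 higher and 268 lower with the percentile taken over all probes, where the median log2 fold change moved from 0.10 to -0.31 and the calls were 3 higher and 4 lower. F_candida_1958 had the smallest p among higher probes, with a log2 fold change of 0.91 (SE 0.16, adjusted p = 0.0592), and averaged 9.30 ± 0.44 in control against 10.16 ± 0.14, 10.35 ± 0.17 and 10.12 ± 0.18 at PCP day 1, 2 and 7. F_candida_2278 had a log2 fold change of 0.81 (SE 0.14, adjusted p = 0.0592), from 4.35 ± 0.12 in control to between 5.12 and 5.22 in the PCP groups. F_candida_2741 was detected on all 3 control arrays, at 3.23 ± 0.62, and on 0 of 9 PCP arrays, which puts it at least 1.48-fold, 1.30-fold and 1.80-fold lower at day 1, 2 and 7 (adjusted p = 0.0592 in the fit of measured values, and 0.994 under normexp, where the log2 fold change was -0.03). F_candida_684 averaged 6.98 ± 0.25 in control and 6.15 ± 0.20, 6.05 ± 0.08 and 5.99 ± 0.55 in the PCP groups (log2 fold change -0.91, SE 0.21, adjusted p = 0.0623). Under normexp the log2 fold change was 0.82 for F_candida_1958, which then passed (adjusted p = 0.0246), 0.28 for F_candida_2278 and -0.57 for F_candida_684 (adjusted p = 0.989 each), and for F_candida_2278 it was 0.15 (adjusted p = 0.138) under normexp with quantile normalization. With the percentile taken over all probes it was 0.49 for F_candida_1958, 0.39 for F_candida_2278 and -1.33 for F_candida_684 (adjusted p = 0.165, 0.203 and 0.0321), and over 27 alternatives the adjusted p of these 3 probes lay between 1.7e-04 and 1.00. The count was 298 (221 higher, 77 lower) without the day 7 control, 64 (60 higher, 4 lower) without PCP day 7 replicate 3, and 1 each without the day 1 and the day 2 control. It was 39 (34 higher, 5 lower) with no day term, 26 (21 higher, 5 lower) with the authors' values and 10 (1 higher, 9 lower) with slide as a block. Slide 3 held all 3 controls and only 1 of the 9 PCP arrays, so treatment and slide are largely tied in this comparison.

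Among exposed animals, the time course was compared between PCP days, which also differ in time in soil. From day 1 to day 2, F_candida_1565 rose by 4.47 log2 units (22.1-fold, SE 0.53, adjusted p = 0.00517), and F_candida_5685, not well above background on any day 1 array, was at least 2.91-fold higher at day 2 (4.29 ± 0.02, adjusted p = 0.0316). F_candida_516 fell from 9.91 ± 0.94 to 5.79 ± 0.83 (17.4-fold, log2 fold change -4.12, SE 0.77, adjusted p = 0.0316), and F_candida_1124 fell from 13.66 ± 0.54 to 10.20 ± 1.15 (log2 fold change -3.46, SE 0.71, adjusted p = 0.0483). In total 5 probes rose and 9 fell, and 118 (8.65%) had an unadjusted p under 0.05. Within slide 1, where 1 day 2 array could be set against the 3 day 1 arrays, the differences of F_candida_1565, F_candida_516 and F_candida_1124 were 3.77, -3.19 and -2.66, and 0 probes passed there or with slide as a block. The count was 50 (25 higher, 25 lower) without PCP day 2 replicate 1, 7 (1 higher, 6 lower) without PCP day 1 replicate 3 and 1, F_candida_1565, without any 1 of the other 4 arrays. It was 6 (1 higher, 5 lower) under normexp, where F_candida_1565, F_candida_5685 and F_candida_516 did not pass (log2 fold changes 1.75, 0.64 and -2.66, adjusted p = 0.852, 0.852 and 0.0530).

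From day 1 to day 7, F_candida_1565 rose by 3.66 log2 units (12.6-fold, SE 0.53, adjusted p = 0.00562), and F_candida_5658 rose from 6.60 ± 0.04 to 8.49 ± 0.30 (3.71-fold, log2 fold change 1.89, SE 0.25, adjusted p = 0.00562). F_candida_721 averaged 5.20 ± 0.68 at day 1 and was not well above background on any day 7 array, at least 7.31-fold lower (adjusted p = 0.00562). F_candida_804 fell from 6.96 ± 0.32 to 3.11 ± 1.93, with detection on 2 of 3 day 7 arrays (log2 fold change -3.85, SE 0.76, adjusted p = 0.0276). In total 2 probes rose and 16 fell, 146 had an unadjusted p under 0.05, and the groups did not overlap for 434 probes (31.8%, chance 10%). Of the probes called from day 1 to day 2 and from day 1 to day 7, 8 were shared and all 8 had the same sign, and both lists use the same day 1 arrays. Unchanged groups simulated with shared day 1 arrays and no slide differences shared 0 calls in 100 draws. That was close to fixed beforehand, because unchanged probes rarely pass the threshold. Independent lists of these lengths would share 0.01 higher and 0.11 lower. Neither value allows for the effects and the shared arrays together. No slide held both groups, and 0 probes passed with slide as a block. In that fit the log2 fold changes were 2.50 (SE 0.99) for F_candida_1565, 2.06 (SE 0.51) for F_candida_5658, -1.39 (SE 0.49) for F_candida_804 and, for values not well above background at day 7, -2.19 (SE 0.86, against -4.12 without the block) for F_candida_721. The count was 8 without PCP day 1 replicate 2 and 9 without PCP day 7 replicate 3. F_candida_804 had adjusted p of 0.0871, 0.137 and 0.0820 without PCP day 1 replicate 1, 2 and 3. Its signal was 4.50, 3.93 and 0.91 on the 3 day 7 arrays, and without PCP day 7 replicate 3, the lowest, its log2 fold change was -2.75 (adjusted p = 0.0259). Under normexp none of these 4 probes passed, with log2 fold changes of 1.21 for F_candida_1565, 1.38 for F_candida_5658, -0.47 for F_candida_721 and -1.18 for F_candida_804 (adjusted p = 1.00, 0.126, 1.00 and 1.00).

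From day 2 to day 7, 0 of 1364 probes passed in limma, the smallest adjusted p was 0.631, and 17 (1.25%) had an unadjusted p under 0.05. Arrays of each group lay on more than 1 slide, so the spread behind these values also holds differences between slides. F_candida_4937 and F_candida_2099 had log2 fold changes of 2.51 (SE 0.76, adjusted p = 0.998) and 1.69 (SE 0.65, adjusted p = 0.998). F_candida_2629 averaged 5.83 ± 0.53 at day 2 and 3.30 ± 0.72 at day 7, where it was detected on 2 of 3 arrays (log2 fold change -2.53, SE 0.52, adjusted p = 0.631). F_candida_5342 had a log2 fold change of -0.66 (SE 0.17, adjusted p = 0.998). Within slide 2, which held 2 arrays of each group, 0 probes passed, and the differences of F_candida_4937, F_candida_2099, F_candida_2629 and F_candida_5342 were 1.83, 0.89, -2.43 and -0.65. Under normexp the log2 fold changes of these 4 probes were 0.82, 1.49, -0.80 and -0.60 (adjusted p = 0.932, 0.932, 0.932 and 0.691), and without PCP day 2 replicate 1 that of F_candida_2099 was 1.06 (adjusted p = 0.880). F_candida_2629 was -0.67 under normexp with quantile normalization (adjusted p = 1.00), and it passed with the percentile taken over all probes (-2.54, adjusted p = 0.0390), with all 5925 probes tested (adjusted p = 0.0147) and with array weights (-2.37, adjusted p = 0.00134).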

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

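The tests of slide, time in soil, scaling and background correction in this part were chosen after the results were seen. The counts over other splits of the arrays were planned before.

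Probes that differed between PCP days were found by testing the difference between days directly, which does not separate PCP from time in soil or slide. Against day 1, the log2 difference at day 2 and day 7 was -2.40 and -2.87 for F_candida_1627, -1.45 and -1.997 for F_candida_513, -1.34 and -1.39 for F_candida_92, and 1.36 and 1.89 for F_candida_5658. F_candida_721, not well above background at day 2 and day 7, was at least 5.10-fold and 7.31-fold lower there, and F_candida_5685, not well above background at day 1, was at least 2.91-fold higher at day 2. At day 2 the log2 difference was -4.12 for F_candida_516 and -3.46 for F_candida_1124. At day 7 it was -3.38 for F_candida_2629 and -3.85 for F_candida_804. Adjusted p-values from limma lay between 0.00293 and 0.0483.

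These probes set the day 1 arrays, all on slide 1, against arrays mostly on other slides. PCP day 2 replicate 1, also on slide 1, was used to weigh a slide difference as the cause. Over the 50 probes called between day 2 and day 1 without that array, it showed a median 0.265 of the day 2 shift (quartiles -0.13 and 0.63). Over the 18 probes called between day 7 and day 1 it showed a median 0.620 of the day 7 shift (quartiles 0.56 and 0.73). Both sets were chosen for a difference from the day 1 arrays, from which the shift of this array is also measured. That choice alone can raise its share. With slide as a block, 0 of the 14 and 0 of the 18 calls passed, all kept their sign, the median ratio of the log2 difference to that without the block was 0.81 and 0.65, and the median SE rose from 0.37 to 0.44 and from 0.27 to 0.47. A slide difference may account for part of both sets of calls, and slide and exposure time cannot be told apart for them, since the share rests on 1 array and no slide held both day 1 and day 7, while time in soil stays open beside PCP exposure.

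F_candida_1565 differed by 4.47 between PCP day 2 and day 1 and by 3.66 between day 7 and day 1. The smaller of its differences within slides 1 and 3 was 3.77 log2 units, against a largest group SD of 0.88. A difference within a slide argues against slide as the whole cause, but only for the PCP arrays compared there. Each of these differences rests on 1 PCP array that also entered the calls, so a large value was likely once the probe was called. With slide as a block, its difference between day 7 and day 1 fell to 2.50, and all 4 of its calls were lost. The SE of its change against control rose from 0.53 to 0.99 at day 2 and 0.75 at day 7. Time in soil without PCP is argued against by the control arrays, where the higher of day 2 and day 7 differed from day 1 by -0.00697. Scaling between arrays is argued against by the lowest log2 fold change against control under quantile normalization, the authors' values and the percentile over all probes, which was 3.21 and past the threshold. Background correction stays open, because normexp, whose offset of 50 compresses dim signals, gave 1.69 and 1.15 at day 2 and day 7 against control and, together with quantile normalization, 1.58 and 1.13, none past the threshold, while day 2 against day 1 passed in the latter setting (1.61, adjusted p = 0.0190) but not under normexp alone (1.75, adjusted p = 0.852). A response to PCP that begins after day 1 may stand beside it as a hypothesis, which 1 control jar per day leaves untested.

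Among the 10 splits of 6 arrays into 3 and 3, too few for a share under 0.05, the real count and the highest other count were 3 and 1 for PCP day 1 versus control, 1 and 13 for day 2 versus control, 1 and 1 for day 7 versus control, 14 and 0 for day 2 versus day 1, 0 and 0 for day 7 versus day 2, and 18 and 0 for day 7 versus day 1. The number of splits with a count as large, the real one included, was 1, 2, 2, 1, 10 and 1 in that order. The split with 13 put PCP day 2 replicate 1 with the controls of day 1 and day 2, and why it gave more calls than the real one was not tested. For PCP versus control adjusted for day, the real count was 0, which each of the 64 choices of 1 array per day as the control reaches by construction, so this comparison says nothing about chance. The highest other count was 158. That choice took PCP day 7 replicate 3 in place of the day 7 control, so its 3 arrays also came from slide 3, and with slide as a block the real choice gave 10 probes.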

How the results depend on the processing

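Counts of called probes over the 7 comparisons kept within 1.5 times of the reported value in 83 of 159 alternatives. These include counts that stayed at 0, and a kept count can hold other probes. Without the day 2 control, the 1 call for day 7 versus control was a lower probe and not F_candida_1565. Named probes kept their side of the threshold in 352 of 470, passed it anew in 31 and lost it in 87, and none changed sign. All 87 losses fall on probes that had passed. The 470 also hold the probes named adjusted for day and for day 7 versus day 2, which had no call to lose. Counts follow in the order PCP day 1, 2 and 7 versus control, adjusted for day, day 2 versus day 1, day 7 versus day 2 and day 7 versus day 1, where 3, 1, 1, 0, 14, 0 and 18 are the reported values, and the cause was not tested unless given. Normexp gave 5, 5, 0, 4, 6, 0 and 8. Quantile normalization gave 21 for day 2 versus control, and normexp with quantile normalization 0 for day 2 and 0 for day 7 versus control. The authors' series table gave 22, 3 and 26 for day 2, day 7 and adjusted for day. The 75th percentile over all probes, added after seeing the data, gave 0, 9, 11, 7, 16, 1 and 22 and moved the median log2 fold change to -0.25, -0.33 and -0.37 in the 3 comparisons with control, against 0.11, 0.11 and 0.09. Testing all 5925 probes gave 3176, 4043, 13, 3839, 27, 1 and 33, with median shifts of 0.78, 0.94 and 0.48 against control. The probes this adds were detected on fewer than 3 arrays. The 75th percentile used for scaling averaged 10.38 in control against 9.71, 9.65 and 9.85 at PCP day 1, 2 and 7. Scaling thus lowers values at the floor more in control than in the PCP groups, so these counts are not read as changes in expression. Probes detected on all arrays gave 0 for day 2 and day 7 versus control and 7 for day 2 versus day 1, over 989 probes tested. Outlier spots kept in gave 0 for day 7 versus control. Without trend the counts were 0 for day 1 and 1 adjusted for day. Array weights gave 632, 936, 550, 677, 540, 23 and 140, but the weights had not converged when the estimation stopped. The same-day control alone, assumed to vary like the PCP groups, gave 279, 0 and 10. Only the 6 arrays compared gave 1 for day 1 and 0 for day 7 versus control, and no day term gave 39.

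Slide as a block gave 0, 2, 2, 10, 0, 0 and 0. Fits within slides, added after seeing the data, gave 0 for day 7 versus control, 0 for day 2 versus day 1 and 0 for day 7 versus day 2, with few arrays each. Slide as a random block, also added, gave 3, 1, 1, 0, 11, 0 and 17. Same replicate numbers did not pair the arrays: in 0 of 6 comparisons did every pair's deviations correlate above 0.1 (range -0.28 to 0.60). The replicate block gave 5, 1, 0, 0, 15, 0 and 26. Leaving out 1 array at a time gave 0 to 187, 1 to 219, 0 to 13, 0 to 298, 1 to 50, 0 to 0 and 8 to 17, and the highest counts against control came without the day 7 control. Scan date was not run, since all slides share 1 date, and set tests were not run without gene names. Signal over background limits what could be measured, as at most 24.5% of probes were detected on an array.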

Other observations

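The tests in this part were chosen after the values were seen. F_candida_5658 averaged 7.16 ± 0.54 log2 units in control, 6.60 ± 0.04 at PCP day 1, 7.96 ± 0.19 at day 2 and 8.49 ± 0.30 at day 7 (SD, n = 3 each), and it was 2.52-fold higher at day 7 than in control without passing the threshold (log2 fold change 1.33, adjusted p = 0.169). F_candida_721 averaged 2.55 ± 0.61 in control and 5.20 ± 0.68 at day 1 (log2 fold change 2.65, adjusted p = 0.104), and was not well above background at day 2 and day 7. F_candida_2629 was 5.03-fold lower at day 7 than in control (log2 fold change -2.33, adjusted p = 0.169).

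PCP and control arrays were also compared over all tested probes at once. The day-adjusted difference between them held 24.4% of the sum of squares. Of the 64 choices of 1 array per day as the control, 2 gave a share as high, the real one included (exact p = 0.0312, highest other choice 30.5%). The 3 controls share slide 3, which this test does not separate from treatment.

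The control probe (+)E1A_r60_3, which targets a spike-in RNA and no transcript of the animals, varied between 0.86 and 4.64 log2 units across the 12 arrays. It averaged 3.58 ± 0.94 in control, 3.60 ± 0.61 at PCP day 1, 1.31 ± 0.39 at day 2 and 1.93 ± 0.49 at day 7 (SD, n = 3 each). On the day 2 arrays and day 7 replicates 2 and 3 it lay below the array's 75th percentile of log2 signal over all probes. At most 24.5% of probes were detected on an array, and whether this probe was well above background is not given. The day 2 and day 7 means may therefore lie at the floor and are not read as measured levels. An unequal amount of spike-in RNA is argued against, because the mean of 8 other spike-in probes had a range 0.154 times as large. That mean lay between 10.77 and 11.35 log2 units, and 1 further spike-in probe was left out of it. The best correlated probe of (+)E1A_r60_3 among 1364, on unscaled signals, was F_candida_1124 (Pearson r = 0.958, Spearman rho = 0.958, each with permutation p = 1e-05 one-sided, the smallest 100000 permutations can give, and a Benjamini-Hochberg adjusted p of at most 0.0136 over the probes). Further called probes followed (+)E1A_r60_3, with r of 0.957 for F_candida_2276, 0.927 for F_candida_516, 0.886 for F_candida_804 and 0.871 for F_candida_92. So did probes without a call, such as F_candida_4347 (r = 0.931). F_candida_1124 and the further called probes given here were each called lower at day 2, day 7 or both than at day 1. Why these falls went along with the signal of a control probe was not tested. A permutation of the highest correlation over all probes gave p = 6.0e-04, r was 0.931 without the 2 arrays farthest from the median of F_candida_1124, and r was 0.953 for deviations from group means. Differences in brightness between arrays, which were not removed here, can enter each of these r and permutation values, and r on scaled signals is not given. Values of (+)E1A_r60_3 that may lie at the floor enter these correlations too. Cross-hybridization of an abundant transcript may explain the signal of (+)E1A_r60_3 where it is above background, as a hypothesis. Any transcript that varies together with F_candida_1124 would do as well, and probe sequences were not used here.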
